A study of Mus musculus with 6 samples.

How the data were processed

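Total RNA of mouse soleus, extracted with Trizol and labelled with biotin, was hybridized to Affymetrix Mouse Gene 1.0 ST arrays: 2 of control mice, 2 of hindlimb suspension and 2 of hindlimb suspension with electroacupuncture. Per the labels, the authors computed the signals by RMA (background correction, quantile normalization and summarization) in Affymetrix Expression Console, with no version given. The deposited values are log2 signals of 35556 transcript clusters, and they were used as they stood. No genome build is given, so no coordinates are reported.

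Each transcript cluster was joined to its gene: 21789 had 1 symbol, 1621 had several and 12146 had no listed gene. Clusters with several or no genes were left out. Of the 21789, 21698 were matched to current symbols by Entrez ID, which changed 0 symbols. For the 999 genes with more than 1 cluster the cluster with the highest mean signal was kept, which left 19938 genes, with no filter on signal. The median of the gene means was 4.58. As a measure of background, chosen after the values were seen, 1027 olfactory receptor genes had a median of 2.10 and a 95th percentile of 3.50, and 13717 genes had a mean above that percentile.

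The arrays were grouped by their labels, and 3 comparisons were made: suspension minus control, suspension with electroacupuncture minus suspension, and suspension with electroacupuncture minus control. A linear model over all 6 arrays was fitted with limma 3.58.1 in R 4.3.3, with moderated variances that follow the mean signal (3 residual and 5.88 prior degrees of freedom). P-values were adjusted by the method of Benjamini and Hochberg, with a threshold of 0.05, and the median standard error of a difference was 0.173 log2. Values are log2 differences with their standard error from limma unless SD is stated. The lists, choices, rule for naming genes and alternatives were set before the data were examined, except where stated.

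In the text, 37 gene lists written from general knowledge (892 entries, 870 distinct genes, 804 of them measured) were tested with camera at a preset correlation of 0.01 between genes, which compares the genes of a list with the other genes. The p-values were adjusted over the 37 lists of a comparison. Camera with a correlation estimated from the residuals and fry, a directional test that compares with no other genes, were run beside it. With the estimated correlation, camera also refers its statistic to the 3 residual degrees of freedom. A larger p in that setting therefore need not come from the correlation between genes. Members were counted past the threshold over all genes and adjusted over the list alone.

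Shared genes were set against independent draws and against 100 simulations of groups without change that used the same control arrays. The opposite change between suspension and treatment was set against 100 simulations in which treatment changed nothing, since the suspension arrays enter both differences. The procedure was tested on simulated data with 200 changed genes in 10 runs. Genes changed 1.5-fold, 2-fold and 4-fold were recovered at 2.84%, 48.7% and 98.5% for suspension minus control and at 3.28%, 45.4% and 97.6% for the treated minus the suspended group, and 5.60% and 4.43% of the calls were false. A list shifted by 0.5 log2 was called in 10 of 10 runs, with a mean of 0.3 other lists per run. The simulated genes varied independently of each other. These runs therefore do not measure the error of camera where the members of a list move together. They also gave every group the same spread, whereas the spread between duplicate arrays differed between the groups of the data. The shares of false calls and of recovered genes therefore need not hold for the data.

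Genes were named by a rule. For each comparison these were the 10 largest rises and 10 largest falls past the threshold whose groups did not overlap, filled by unadjusted p among genes at or above the median signal where fewer passed, up to 4 members of each described list with the smallest p, and a fixed set of genes of interest. Symbols of predicted genes and clone names were passed over. Ciart, Ccl17, Mmp13 and Kera in the treated minus the suspended group, Chad in the treated group minus control, and Trp53inp1 and the genes that differ between arrays of a group fell outside the rule and were chosen after their values were seen.

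The alternatives were other variance priors, array weights, a filter on the median signal, quantile normalization again, median centring, cyclic loess, the mean of all clusters of a gene, every cluster by itself, a fit of the compared groups alone, a block for replicate number, a looser threshold, a fold threshold, other tests of lists and each array left out in turn.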

Results

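Gene expression was measured in mouse soleus, a postural calf muscle rich in slow fibres, on 6 arrays that fell into 3 groups of 2: control, hindlimb suspension, and hindlimb suspension with electroacupuncture. Hindlimb suspension lifts the hind limbs off the ground so that their muscles carry no weight and waste, and electroacupuncture passes a current through acupuncture needles. All samples were labelled as male C57BL/6 mice of 8 weeks. The signals were compared for 19938 genes, with array medians from 4.13 to 4.19 on the log2 scale. The number of arrays limits the precision of every value. Mean rank correlation of an array with the others ran from 0.982 in control array 1 to 0.988 in array 2 of the electroacupuncture group. The first principal component held 37.7% of the variance and parted the control arrays from the 4 suspended arrays. The second held 23.4% and parted the control arrays from each other. The labels do not say whether the arrays of a group came from separate mice, and the design text says only that hybridizations were run in duplicate. The p-values therefore measure the spread between arrays, which need not be the spread between mice.

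The comparison of suspension with control addressed the effect of unloading on the soleus. In suspended soleus 5 of 15 fast-fibre contractile genes, 2 of 18 genes of glycolysis and the atrophy ubiquitin ligase gene Fbxo32 rose. Signals fell for the slow-muscle stretch sensor Ankrd2, for Ppargc1a, the coactivator of mitochondrial biogenesis, for the ketone body enzyme gene Bdh1, and for 6 of 28 heat shock and 4 of 23 fatty acid genes. Ddit4l, an inhibitor of mTOR signalling, rose from 7.77 ± 0.20 to 10.09 ± 0.05 (log2 signal, mean ± SD, n = 2), a difference of 2.32 ± 0.18 (SE). Bdh1, the mitochondrial enzyme that interconverts ketone bodies, fell from 7.90 ± 0.04 to 5.50 ± 0.02, which was 5.25-fold. In all, 209 of 19938 genes passed adjusted p under 0.05, 107 higher and 102 lower in the suspended group, 110 of them changed at least 2-fold and 9 at least 4-fold. The balance of directions depended on the control arrays and on the scaling, with 86 higher and 142 lower without control array 1 and 207 higher and 94 lower without control array 2. It was 131 and 178 after cyclic loess, 139 and 178 with quantile normalization again and 73 and 85 with each array centred on its median.

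The contractile genes differed by fibre type. Of 15 measured fast-fibre contractile genes, 5 rose and 1 fell, with 9 higher and 2 lower when adjusted over the list alone. Actn3, the Z-disc actinin of fast fibres, rose by 2.28 ± 0.23 log2 (difference ± SE, adjusted p = 0.00618), and the fastest myosin heavy chain gene, Myh4, rose by 2.12 ± 0.33 (adjusted p = 0.0269), with signals of 10.76 and 9.46 on the control arrays. The parvalbumin gene Pvalb (adjusted p = 0.0145), Myoz1 (log2 difference 1.04) and the IIX myosin gene Myh1 (0.86) also rose. Myh2, the myosin of the oxidative fast IIA fibres, fell by 2.00 ± 0.29 (adjusted p = 0.021). The list had a median of 0.47 and a camera adjusted p of 6.73e-06, with an adjusted p = 0.235 with an estimated correlation. Its fry adjusted p was 0.0311.

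Of 14 slow-fibre contractile genes, 2 fell, 10 when adjusted over the list alone. The 2 were Ankrd2, which is induced by stretch (log2 difference -1.53 ± 0.16, adjusted p = 0.00641), and Casq2, the calsequestrin of slow and cardiac muscle (-1.27 ± 0.13, adjusted p = 0.00618). The mechanosensor gene Csrp3 (-1.71, adjusted p = 0.0728), slow troponin I Tnni1 (-0.82, adjusted p = 0.166) and the slow myosin heavy chain gene Myh7 (-0.14 ± 0.18, adjusted p = 0.815) did not pass. The slow-fibre list had a median of -0.80 (camera adjusted p = 1.69e-10; adjusted p = 0.396 with an estimated correlation). The difference of Myh7 was 0.05 without control array 2. Among 26 genes of calcium handling and excitation-contraction coupling, 4 rose and 1, Casq2, fell, with 9 higher and 4 lower when adjusted over the list alone. Those that rose included the L-type calcium channel subunits Cacng1 (1.35) and Cacna1s (0.90) and the release channel Ryr1 (0.89). The list (median 0.13, camera adjusted p = 0.00791; adjusted p = 0.413 with an estimated correlation) was no longer past the threshold without control array 1 (adjusted p = 0.071).

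Among 23 ubiquitin ligases and other atrophy-induced genes, 3 rose, 5 when adjusted over the list alone. They were Fbxo32, which encodes the ligase atrogin-1 (1.35 ± 0.15, adjusted p = 0.00854), its relative Fbxo31 (1.25) and the stress gene Gadd45a (1.24). The other main atrophy ligase gene, Trim63 (MuRF1), differed by 0.16 ± 0.18 (adjusted p = 0.805), and by -0.10 without suspension array 1. Myostatin (Mstn), a brake on muscle growth, differed by 0.56 (adjusted p = 0.166), at a signal of 3.42 in control that lay below the 95th percentile of 1027 olfactory receptor genes, 3.50. The atrophy list had a median of 0.22 (camera adjusted p = 1.68e-04; adjusted p = 0.413 with an estimated correlation). Of 39 proteasome subunits none passed, and their median was 0.05 (camera adjusted p = 0.597), with an adjusted p of 0.0207 without control array 2. Of 27 autophagy and lysosome genes, 1 rose, the autophagosome gene Map1lc3a (0.83), and 2 when adjusted over the list alone. That list had a median of 0.12 (camera adjusted p = 0.0106; adjusted p = 0.686 with an estimated correlation), with an adjusted p of 0.507 without control array 1 and 0.182 without suspension array 1.

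Lists of oxidative metabolism had medians below 0 in the suspended soleus and that of glycolysis a median above 0. Of 23 genes of fatty acid uptake and oxidation, 4 fell, 10 when adjusted over the list alone, and all 23 differences were below 0. Fabp3, which carries fatty acids within muscle cells, fell by 1.79 ± 0.25 log2 (adjusted p = 0.0189), with smaller falls of Acaa2 (-0.83), Eci1 (-0.73) and Hadha (-0.70), enzymes of beta-oxidation. The list had a median of -0.39 (camera adjusted p = 2.23e-11; adjusted p = 0.413 with an estimated correlation). Of 15 PGC-1 and nuclear receptor regulators, 4 fell, 5 when adjusted over the list alone: Nr4a3 (-2.20), Ppargc1a (-1.56), the angiogenic factor Vegfa (-1.37) and Ppara (-1.14). Their list had a median of -0.19 (camera adjusted p = 5.57e-06; adjusted p = 0.396 with an estimated correlation).

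None of 68 oxidative phosphorylation genes passed over all genes. Of them, 6 were lower when adjusted over the list alone, and 62 differences were below 0. Cytochrome c (Cycs, -0.68, adjusted p = 0.0588) and Ndufb6 (-0.63, adjusted p = 0.077) were among them. The list had a median of -0.22 (camera adjusted p = 5.79e-11; adjusted p = 0.639 with an estimated correlation). The 18 tricarboxylic acid cycle genes had no call over all genes, 5 lower when adjusted over the list alone, and a median of -0.30 (camera adjusted p = 3.48e-04; adjusted p = 0.441 with an estimated correlation; 0.0689 without control array 2). Of 18 genes of glycolysis and glycogen, 2 rose, Pfkfb3 (1.38), whose product drives glycolytic flux, and the glycogen phosphorylase gene Pygm (0.71), with 9 higher and 1 lower when adjusted over the list alone (median 0.35, camera adjusted p = 5.59e-06; adjusted p = 0.413 with an estimated correlation).

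Heat shock proteins and chaperones showed the lowest camera p of the 37 lists in this comparison. Of 28 measured, 6 fell, 17 when adjusted over the list alone, and 26 differences were below 0. Hspa1l, an HSP70 gene, fell by 1.62 ± 0.17 (adjusted p = 0.00618), the HSP40 gene Dnajb4 by 1.13, the small heat shock gene Hspb7 by 1.02 and the endoplasmic reticulum chaperone gene Hspa5 by 0.88. The inducible HSP70 gene Hspa1a differed by -1.14 ± 0.28 (adjusted p = 0.113). The list had a median of -0.50 (camera adjusted p = 1.65e-16; adjusted p = 0.0842 with an estimated correlation), and fry, which tests whether members move one way, gave an adjusted p of 0.0311. Of 17 circadian clock genes, Rora rose (0.84, adjusted p = 0.028), 6 were higher when adjusted over the list alone, and 16 differences were above 0 (median 0.32, camera adjusted p = 5.57e-06; adjusted p = 0.235 with an estimated correlation). None of 7 genes of polyamine metabolism passed, 2 were lower when adjusted over the list alone, and all 7 differences were below 0, among them Sat1 at -0.62 (median -0.28, camera adjusted p = 0.00461; adjusted p = 0.396 with an estimated correlation). None of 21 genes of cholesterol and lipid synthesis passed, over all genes or adjusted over the list alone (median 0.12, camera adjusted p = 0.036; adjusted p = 0.686 with an estimated correlation), and the list lost its call without control array 1 (adjusted p = 0.569) and without suspension array 1 (0.522), with cyclic loess (0.0588) and with the filter on the median signal (0.0964).

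For matrix and tendon genes the suspension arrays differed from each other. Of 18 fibroblast and tendon markers 3 fell, 7 when adjusted over the list alone: Chad, a cartilage and tendon matrix protein gene (-2.48 ± 0.23, adjusted p = 0.00496), Kera, the keratocan gene (-2.09 ± 0.19, adjusted p = 0.00496), and the tendon marker Tnmd (-1.94 ± 0.15, adjusted p = 0.00307). The list mean lay at -0.24 and -0.88 from the control mean in suspension arrays 1 and 2. Its camera adjusted p was 9.31e-06 (median -0.38; adjusted p = 0.413 with an estimated correlation), and 0.286 without suspension array 2. Of 43 genes of collagens and matrix, 2 fell, P4ha1 (-0.91), an enzyme of collagen hydroxylation, and Col12a1 (-0.94). Adjusted over the list alone, 8 were lower. Col1a1 differed by -1.62 ± 0.45 (adjusted p = 0.157). The collagen list mean lay at 0.10 and -0.80 from the control mean in suspension arrays 1 and 2, so its median of -0.27 (camera adjusted p = 5.57e-06; adjusted p = 0.686 with an estimated correlation) rested on array 2. Without that array the test turned upward with an adjusted p of 0.991.

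Macrophage markers lay at 0.65 and -0.08 from the control mean in suspension arrays 1 and 2. None of 22 passed, and their camera adjusted p of 0.0189 (median 0.29; adjusted p = 0.903 with an estimated correlation) became 0.367 without control array 1 and 0.0898 for macrophage markers at or above the median signal, and turned downward without suspension array 1 (0.394). The 14 adipocyte markers lay at -0.58 and 0.58 from the control mean in control arrays 1 and 2. None passed, and their median of -0.55 (camera adjusted p = 0.00221; adjusted p = 0.686 with an estimated correlation) turned upward without control array 2 (adjusted p = 0.351).

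Other large changes lay outside these lists. Chac1, a glutathione-degrading enzyme gene, rose by 2.27 ± 0.42 (adjusted p = 0.0471), the carbonic anhydrase gene Car1 by 2.02, the amino acid transporter gene Slc43a1 by 1.84, the melanocortin receptor gene Mc5r by 1.83, the stress gene Gadd45b by 1.64, the myosin light chain kinase gene Mylk2 by 1.61 and the immune ligand gene H60b by 1.61. The control signals of Car1 (3.10) and H60b (2.73) lay below the 95th percentile of the olfactory receptor genes, so their folds depend on the background level. The deubiquitinase gene Otud1 fell by 1.92, the phosphatase gene Inpp5j by 1.81 and the pentraxin gene Ptx4 by 1.78. The remaining 19 lists did not pass camera, among them satellite cell and myogenic factors (median 0.14, camera adjusted p = 0.229) and the neuromuscular junction and denervation response (0.08, 0.369). Of 8 called lists a leave-out of 1 array ended or turned the call, as given above, and 10 kept it without each array in turn. All 18 lost it with the estimated correlation, a setting that also rests on 3 residual degrees of freedom.

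**Figure D1:**
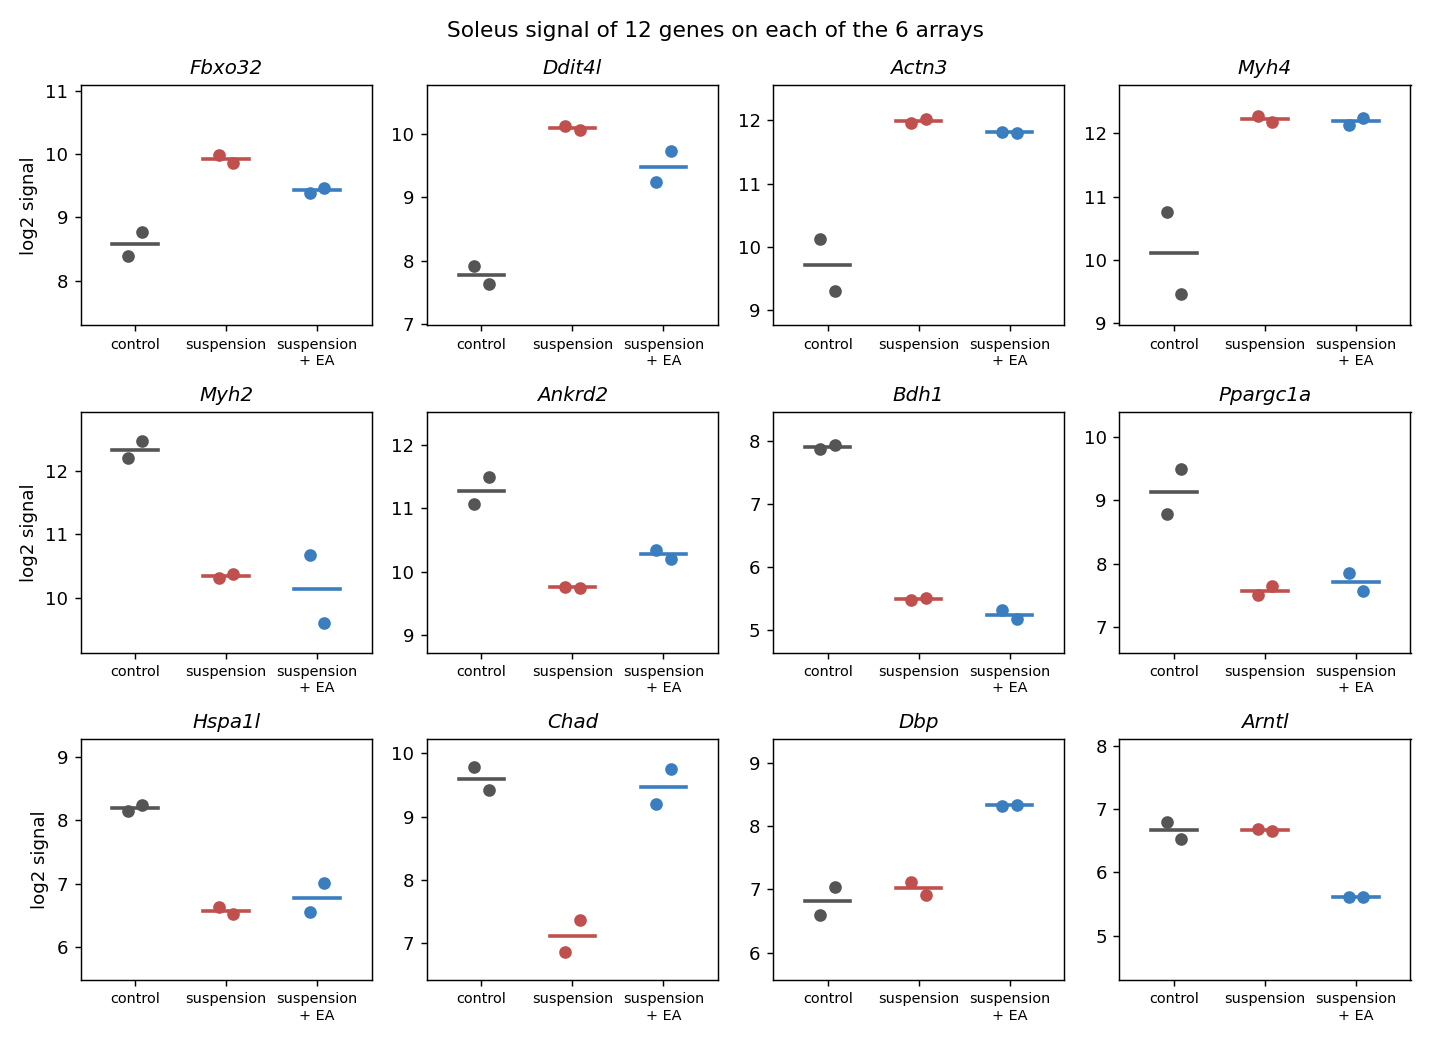
Log2 signal of 12 genes on each of the 6 arrays, with each point an array and each line the mean of its group of 2; every panel spans the same number of log2 units, but the range shown differs between panels. Fbxo32, Ddit4l, Actn3 and Myh4 lay higher and Myh2, Ankrd2, Bdh1, Ppargc1a and Hspa1l lower in both suspended groups than in control, while Chad lay near its control level (9.60) in the electroacupuncture group (9.47) and Dbp and Arntl stood apart in that group.

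The test was limma over 6 arrays with 3 residual degrees of freedom, and 2537 genes had an unadjusted p under 0.05, against 996.9 by chance. The count fell to 16 without suspension array 1, 42 without suspension array 2 and 67 without either electroacupuncture array, where 2 residual degrees of freedom were left. It was 228 and 301 without control arrays 1 and 2. Every fit with an array left out had 2 residual degrees of freedom, also those without a control array, where the count did not fall. The main fit pooled the spreads of all 3 groups. Between duplicate arrays the SD of the difference was 0.357 in control, 0.293 in suspension and 0.251 in the electroacupuncture group. The electroacupuncture arrays do not enter this comparison, and with the groups compared fitted alone 68 genes passed. With every transcript cluster tested by itself 1 gene passed, Bdh1. The larger number of tests alone lowered the count to 118. The clusters without a single symbol were also noisier (median residual SD 0.274 against 0.166), and the prior degrees of freedom went from 5.88 to 3.07. Of 47 genes taken by the naming rule that passed, 1, Bdh1, kept its call in every setting. Another 7 (Chad, Kera, Tnmd, Ddit4l, Gadd45b, Mylk2 and Nr4a3) lost it with every cluster tested by itself and in no other setting, and 37 lost it without suspension array 1.

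The comparison of the electroacupuncture group with suspension alone addressed the effect of the treatment in unloaded muscle. No gene passed adjusted p under 0.05. The gene nearest to it was Chad, with 9.47 ± 0.39 (log2 signal, mean ± SD, n = 2) in the electroacupuncture group against 7.11 ± 0.35 in suspension, a difference of 2.36 ± 0.23 log2 or 5.14-fold (adjusted p = 0.0601). Clock genes came next, with Dbp, an output of the clock, at 1.31 ± 0.17 (adjusted p = 0.174) and Arntl, which encodes the clock activator BMAL1, at -1.05 ± 0.14 (adjusted p = 0.204). The embryonic myosin gene Myh3 (1.10, adjusted p = 0.269) and cardiac actin Actc1 (0.90, adjusted p = 0.367) did not pass either. In limma 612 genes had an unadjusted p under 0.05, against 996.9 by chance. Between duplicate arrays, the SD across genes of the difference was 0.357 in control, 0.293 in suspension and 0.251 in the electroacupuncture group. The fit pooled these spreads, though the control arrays do not enter this difference. In simulated data of this size, 3.28% of genes changed 1.5-fold, 45.4% of those changed 2-fold and 97.6% of those changed 4-fold were recovered. That simulation gave every group the same spread, and a lack of calls does not show a lack of change.

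The atrophy genes showed differences that did not pass: Fbxo32 -0.50 ± 0.15, Trim63 -0.64 ± 0.18 and Mstn -0.17 ± 0.16, each with an adjusted p of 1.00. The list of atrophy-induced genes had a median of 0.00 and a camera adjusted p of 0.278, and 1 member, Asb2 (-0.56), was lower when adjusted over the list alone. Fast myosin genes lay within their error of the suspension level, at -0.04 ± 0.33 for Myh4 and -0.20 ± 0.29 for Myh2, and these values were 0.01 without suspension array 1 (Myh4) and 0.34 without electroacupuncture array 2 (Myh2). Stretch-responsive Ankrd2 differed by 0.52 ± 0.16 and Csrp3 by 0.90 ± 0.36 (adjusted p = 1.00 for both). The slow-fibre list had a median of 0.23 (camera adjusted p = 0.00471; adjusted p = 0.631 with an estimated correlation), and its mean lay at -0.80 and -0.35 from the control mean in electroacupuncture arrays 1 and 2. That call ended without suspension array 1 (adjusted p = 0.113) and without electroacupuncture array 2 (0.966). The 7 embryonic and neonatal contractile genes had a median of 0.48 (camera adjusted p = 2.36e-05; adjusted p = 0.561 with an estimated correlation), and fry gave an adjusted p of 0.00322. Myh3 and Actc1 were higher when adjusted over the list alone. The list of neuromuscular junction and denervation response, with Chrnb1, a subunit of the acetylcholine receptor, at 0.42, had a median of 0.11 over 21 members (camera adjusted p = 0.0088; adjusted p = 0.561 with an estimated correlation; 0.181 without suspension array 2 and 0.596 without electroacupuncture array 1).

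Clock genes parted in direction. Of 17 measured, 6 were higher and 2 lower when adjusted over the list alone, and none passed over all genes. Besides Dbp, Per2 differed by 0.81, and besides Arntl the repressor gene Nfil3 differed by -0.88. The list had a median of 0.30 (camera adjusted p = 0.00279; adjusted p = 0.561 with an estimated correlation). Endothelial cell markers were lower in 15 of 16 cases, with a median of -0.25 (camera adjusted p = 9.85e-08; adjusted p = 0.561 with an estimated correlation), and 1 was lower when adjusted over the list alone, the VEGF receptor gene Kdr (-0.69). The markers Emcn (-0.43), Ptprb (-0.39) and Tek (-0.37) did not pass. Immediate early genes had a median of -0.13 over 27 members (camera adjusted p = 0.00287; adjusted p = 0.631 with an estimated correlation), with Ccn1 at -0.76 lower when adjusted over the list alone, and lost the call without suspension array 1 (adjusted p = 0.749) and without electroacupuncture array 1 (0.124). Glucocorticoid-induced genes had a median of 0.13 over 21 members (camera adjusted p = 0.00587; adjusted p = 0.631 with an estimated correlation), with Tsc22d3 at 0.69, and turned downward without suspension array 2 (adjusted p = 0.395) and lost the call without electroacupuncture array 2 (0.557). The 68 oxidative phosphorylation genes had a median of -0.07 (camera adjusted p = 0.00735; adjusted p = 0.702 with an estimated correlation), which was 0.142 without suspension array 2 and turned upward without electroacupuncture array 1 (0.934). The list of cholesterol and lipid synthesis had a median of -0.15 over 21 members (camera adjusted p = 0.0428; adjusted p = 0.631 with an estimated correlation), and lost its call without either control array (adjusted p = 0.0588 and 0.0583), suspension array 1 (0.863) or electroacupuncture array 1 (0.206), with cyclic loess (0.0536) and with the filter on the median signal (0.238).

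Of 18 fibroblast and tendon markers 4 were higher when adjusted over the list alone, among them Chad, Tnmd (0.75) and the fibromodulin gene Fmod (0.85), and Kera differed by 0.20 ± 0.19. The list had a median of 0.29 (camera adjusted p = 8.08e-07; adjusted p = 0.561 with an estimated correlation), and an adjusted p of 0.855 without suspension array 2. Among the single genes with the smallest p outside the lists, none of which passed, were Timp3 (0.85, adjusted p = 0.337), Mfap4 (0.87) and Prelp (0.88, adjusted p = 0.471 for both). Macrophage markers lay at 0.80 and 0.31 from the control mean in electroacupuncture arrays 1 and 2. Their median was 0.33 over 22 members (camera adjusted p = 2.40e-04; adjusted p = 0.631 with an estimated correlation), and the call turned downward without suspension array 2 (adjusted p = 0.395) and ended without electroacupuncture array 1 (0.852). The 14 adipocyte markers had a median of 0.37 (camera adjusted p = 0.00114; adjusted p = 0.631 with an estimated correlation), and they differed between the control arrays, which do not enter this difference. Of 13 Schwann cell and nerve markers 12 were above 0, with a median of 0.07 (camera adjusted p = 0.0139; adjusted p = 0.561 with an estimated correlation), and the call ended without either suspension array (adjusted p = 0.0879 and 0.0778), without electroacupuncture array 1 (0.196) and with the filter on the median signal (0.467). The 43 genes of collagens and matrix had a median of -0.06 while the test pointed upward (camera adjusted p = 0.994), and it turned to 1.17e-15 upward without suspension array 1 and 1.02e-14 downward without suspension array 2.

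Up to 4 genes passed in some settings. Chad had an adjusted p between 0.0208 and 0.846 over the settings tried. It passed with a robust variance prior (adjusted p = 0.0415), and Chad, Dbp, Arntl and the chemokine gene Ccl17 passed with array weights. With the groups compared fitted alone, or without control array 1 or control array 2, the same 3 genes passed: Chad, Dbp and the clock gene Ciart (1.80 log2). Without suspension array 2, Mmp13 alone passed (-6.25, adjusted p = 0.00695), a collagenase gene with a signal of 10.02 on suspension array 1 and 4.09 on suspension array 2. Its signals of 4.29 and 3.24 on the electroacupuncture arrays lay near the 95th percentile of the olfactory receptor genes (3.50), so the size of this difference rests on 1 array and on the background level. Ccl17, Ciart, Mmp13 and, above, Kera were named here after their values were seen. Without electroacupuncture array 1 the number of lists past camera fell from 13 to 8, and 4 lists kept their call without each array in turn: endothelial, embryonic and neonatal contractile, adipocyte and clock.

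**Figure D2:**
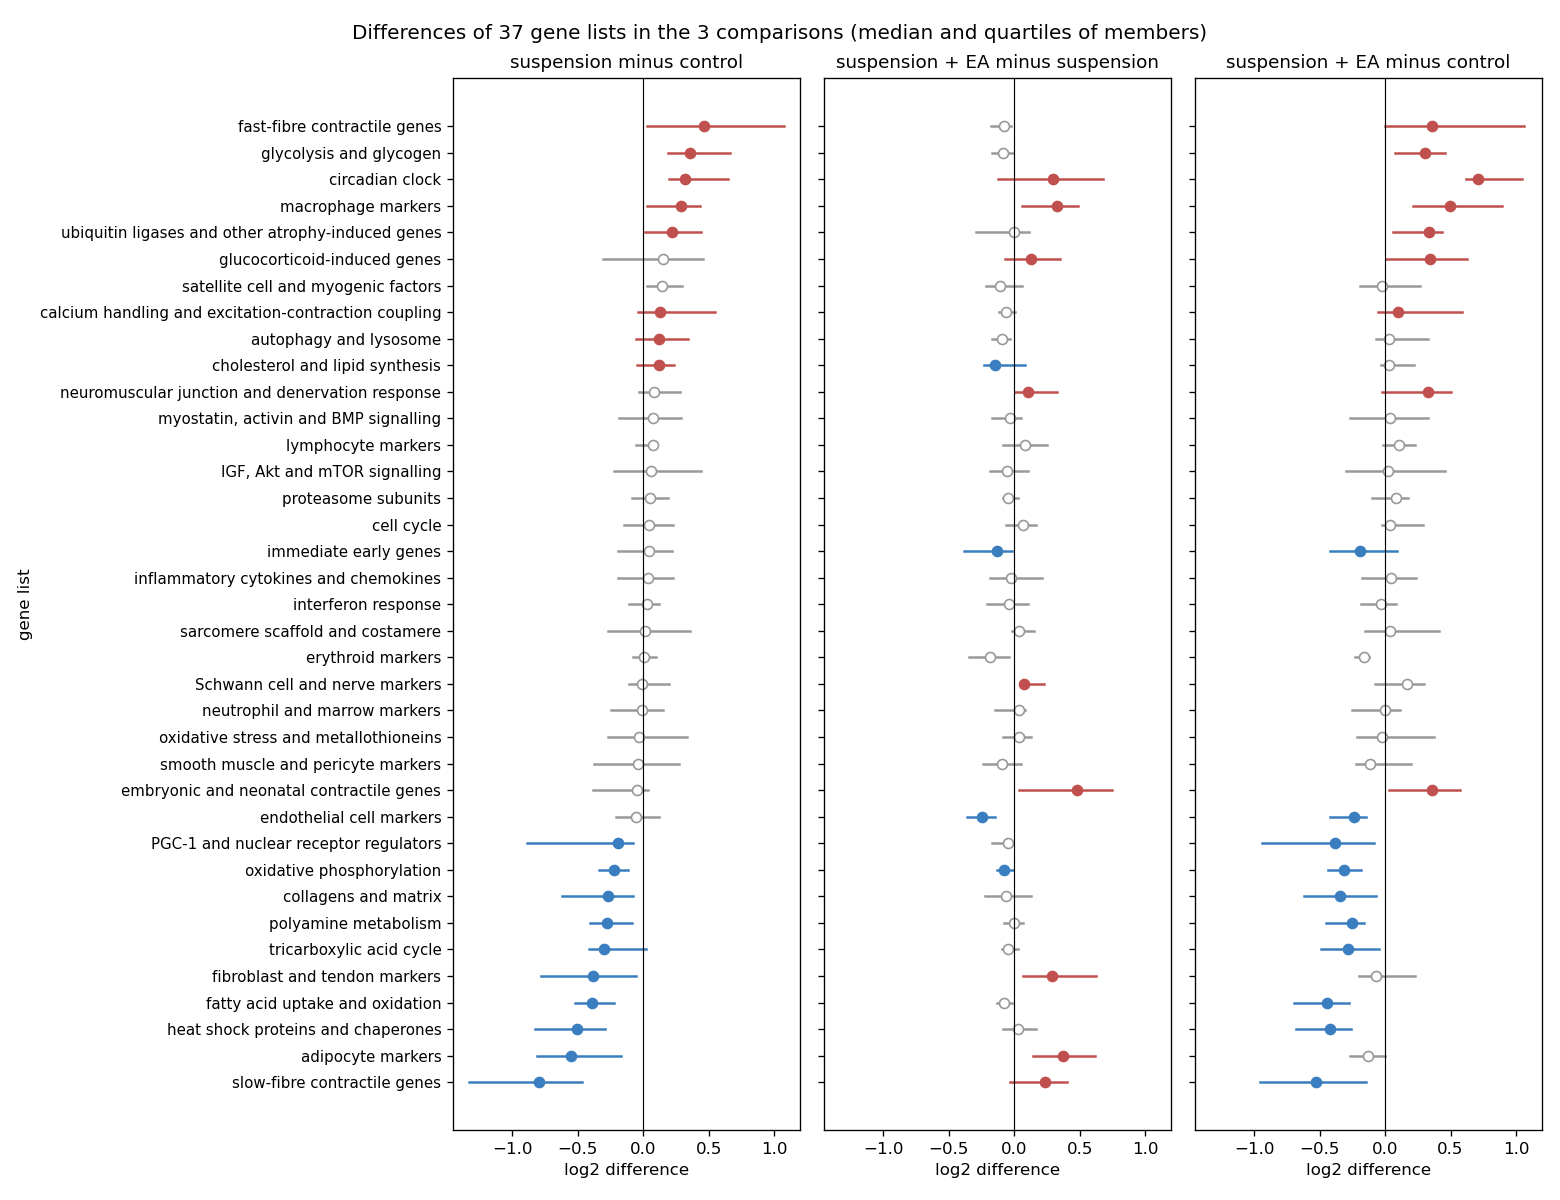
Median (dot) and quartiles (line) of the log2 differences of the members of 37 gene lists in the 3 comparisons; filled red and blue dots mark lists with a camera adjusted p under 0.05 in the higher and lower direction at the preset correlation, and open grey dots the others. Heat shock proteins and chaperones had medians of -0.50, 0.03 and -0.42 from left to right, and the circadian clock 0.32, 0.30 and 0.71.

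The comparison of the electroacupuncture group with control showed how far treated, suspended soleus stood from loaded muscle. The contractile and metabolic pattern of suspension was again present: Actn3 rose by 2.10 ± 0.23 log2, Myh4 by 2.08 ± 0.33 and Myh1 by 0.87, while Myh2 fell by 2.20 ± 0.29, Bdh1 by 2.65 ± 0.13 and Fabp3 by 2.04 ± 0.25. Fbxo32 rose by 0.85 ± 0.15 (adjusted p = 0.0404), and Trim63 differed by -0.49 ± 0.18 (adjusted p = 0.307). Ankrd2 fell by 1.01 ± 0.16 (adjusted p = 0.0285) and Ppargc1a by 1.42 ± 0.22 (adjusted p = 0.0252), whereas Myh7 differed by -0.02 ± 0.18, and by 0.18 without control array 2 and 0.16 without electroacupuncture array 1. In limma 206 of 19938 genes passed, 89 higher and 117 lower, 117 of them at least 2-fold and 10 at least 4-fold, and with each array centred on its median the split was 55 higher and 111 lower. It was 67 higher and 139 lower without control array 1 and 189 higher and 110 lower without control array 2.

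Of 17 clock genes, 3 rose, among them Dbp (1.51 ± 0.17, adjusted p = 0.00871) and Per3 (1.49), while Arntl (-1.05 ± 0.14, adjusted p = 0.015) and Nfil3 (-1.17) fell. Adjusted over the list alone, 13 were higher and 2 lower (median 0.71, camera adjusted p = 8.12e-10; adjusted p = 0.162 with an estimated correlation; fry adjusted p = 0.0381). Of 16 endothelial markers Kdr fell (-1.28, adjusted p = 0.0135), and 4 were lower when adjusted over the list alone. Their median was -0.24 (camera adjusted p = 1.35e-05; adjusted p = 0.379 with an estimated correlation). None of 22 macrophage markers passed, and 4 were higher when adjusted over the list alone. Their median was 0.50 (camera adjusted p = 1.75e-06; adjusted p = 0.569 with an estimated correlation), with 0.80 and 0.31 on electroacupuncture arrays 1 and 2.

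Of 21 glucocorticoid-induced genes, the glutamine synthetase gene Glul rose (0.94), with 4 higher and 1 lower when adjusted over the list alone. This list (median 0.34, camera adjusted p = 0.00446; adjusted p = 0.569 with an estimated correlation) lost its call without electroacupuncture array 2 (adjusted p = 0.17). The 21 genes of neuromuscular junction and denervation response (median 0.33, 1 higher when adjusted over the list alone, camera adjusted p = 0.00465; adjusted p = 0.379 with an estimated correlation) lost the call without control array 1 (0.0928) and electroacupuncture array 1 (0.154). The 7 embryonic and neonatal contractile genes had a median of 0.36 (camera adjusted p = 0.025, 0.379 with an estimated correlation, fry adjusted p = 0.0209). Their camera call was lost without either control array, and 1, Myh3 (0.81), was higher when adjusted over the list alone. Of 27 immediate early genes Nr4a3 fell (-2.47) and 5 were lower when adjusted over the list alone (median -0.19, camera adjusted p = 0.0196; adjusted p = 0.592 with an estimated correlation), and the call ended without control array 2 (0.474) and electroacupuncture array 1 (0.109).

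Of 18 fibroblast and tendon markers, Kera (-1.89 ± 0.19, adjusted p = 0.00764), Tnmd (-1.20, adjusted p = 0.0111) and the tendon transcription factor gene Scx (-0.96, adjusted p = 0.0334) fell, and 1 was higher and 3 lower when adjusted over the list alone. Chad differed by -0.12 ± 0.23 (adjusted p = 0.899), with 0.06 without control array 1 and 0.15 without electroacupuncture array 1, and was named here after its values were seen. The median of the list was -0.07 (camera adjusted p = 0.172). Collagens and matrix had a median of -0.34 over 43 members, with none passing over all genes and 7 lower when adjusted over the list alone (camera adjusted p = 2.41e-06; adjusted p = 0.569 with an estimated correlation).

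Metabolic and stress lists kept the direction they had in suspension alone. Of 68 oxidative phosphorylation genes Ndufc1 fell (-0.67), and 17 were lower when adjusted over the list alone (median -0.32, camera adjusted p = 1.19e-16; adjusted p = 0.428 with an estimated correlation). Fatty acid uptake and oxidation had 4 of 23 that fell, 14 when adjusted over the list alone (median -0.44, camera adjusted p = 7.56e-14; adjusted p = 0.379 with an estimated correlation), and the PGC-1 list had 4 of 15, 7 when adjusted over the list alone (median -0.38, camera adjusted p = 6.01e-08; adjusted p = 0.340 with an estimated correlation). Heat shock proteins and chaperones had 6 of 28 that fell, among them Dnajb4 (-1.24), Hspa1l (-1.41) and the mitochondrial chaperonin gene Hspe1 (-0.90), and 15 when adjusted over the list alone (median -0.42, camera adjusted p = 9.29e-16; adjusted p = 0.0927 with an estimated correlation; fry adjusted p = 0.0319). The tricarboxylic acid cycle had a median of -0.29, with 1 of 18 higher and 8 lower when adjusted over the list alone (camera adjusted p = 1.70e-05, 0.379 with an estimated correlation). Polyamine metabolism had a median of -0.25 (camera adjusted p = 0.00365, 0.340 with an estimated correlation). None of its 7 genes passed over all genes, and 3 were lower when adjusted over the list alone.

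Glycolysis and glycogen had 1 of 18 that rose, Pfkfb3 (1.60), with 6 higher and 2 lower when adjusted over the list alone (median 0.31, camera adjusted p = 3.98e-04; adjusted p = 0.450 with an estimated correlation). The slow-fibre list had 3 of 14 that fell, Ankrd2, Casq2 and the slow light chain gene Myl3 (adjusted p = 0.0377), 4 when adjusted over the list alone (median -0.53, camera adjusted p = 1.75e-06; adjusted p = 0.379 with an estimated correlation). Of 15 fast-fibre genes 5 rose and 1 fell, 8 and 1 when adjusted over the list alone (median 0.36, camera adjusted p = 1.18e-04; adjusted p = 0.265 with an estimated correlation; fry adjusted p = 0.0337). Atrophy-induced genes had 2 of 23 that rose, Fbxo32 and Gadd45a (1.25), with 6 higher and 1 lower when adjusted over the list alone (median 0.33, camera adjusted p = 6.73e-04; adjusted p = 0.379 with an estimated correlation). The list of calcium handling and excitation-contraction coupling (median 0.10, 2 of 26 higher and 1 lower, 8 and 3 when adjusted over the list alone, camera adjusted p = 0.0417; adjusted p = 0.450 with an estimated correlation) lost its call without control array 1 (0.222), either suspension array (0.0505 and 0.0508) or electroacupuncture array 2 (0.208), and also with the replicate block (0.0625), cyclic loess (0.118) and the filter on the median signal (0.0687).

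Outside the lists, the methyltransferase gene Inmt rose by 2.04 ± 0.17, Car1 by 1.91, the synaptic vesicle gene Sv2b by 1.75, Wfdc17 by 1.74, the death receptor gene Eda2r by 1.73, Ddit4l by 1.71, Mc5r by 1.63 and Cep85l by 1.61. Lrrc52 fell by 2.38 ± 0.43, the phosphatase regulator genes Ppp1r27 by 2.23 and Ppp1r3c by 1.79, Otud1 by 2.05 and Tmem171 by 1.91. In this comparison 2553 genes had an unadjusted p under 0.05, against 996.9 by chance. The count fell to 9 and 2 without electroacupuncture arrays 1 and 2 and to 124 and 113 without suspension arrays 1 and 2. It was 206 and 299 without control arrays 1 and 2, and 1 gene, Bdh1, passed with every transcript cluster tested by itself (124 genes from the larger number of tests alone). Of 50 named genes that passed, 48 lost the call without electroacupuncture array 2 and 42 without array 1.

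Both suspended groups changed in the same direction against control. Of the genes past the threshold in each comparison, 131 were shared, 60 higher and 71 lower in both and 0 in opposite directions, against 0.478 and 0.599 for lists drawn independently and a mean of 0.18 (highest 2) in 100 simulations of unchanged groups with the same control arrays. Across genes, which are not independent replicates, the differences of both groups from control correlated with r = 0.790, against 0.50 in the simulated groups. In the simulated groups no gene truly changed, so a gene could be called only by error. They therefore cannot show how many of the 131 shared genes come from the shared controls. Part of the excess may come from them.

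**Figure D3:**
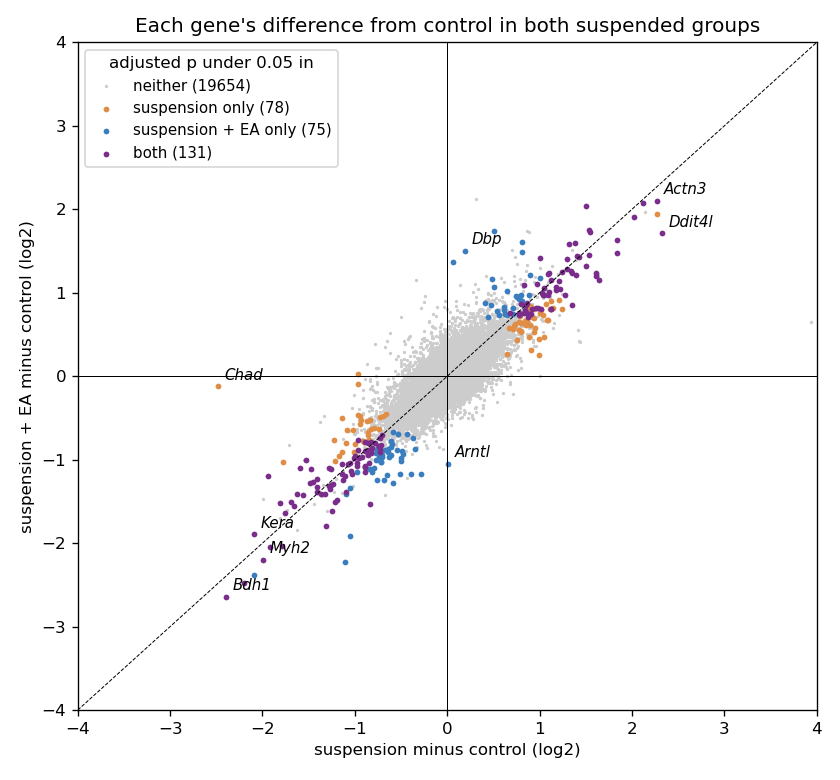
Log2 difference from control of each of 19938 genes in suspension (horizontal axis) and in suspension with electroacupuncture (vertical axis), with colours for the genes at adjusted p under 0.05 in 1 or both comparisons and a dashed line of equal differences. The 131 genes past the threshold in both lay in the lower left and the upper right of the plot, and Chad lay at -2.48 on the horizontal and -0.12 on the vertical axis.

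The last comparison asked whether the genes changed by suspension moved the other way with electroacupuncture. Of the 209 genes, 147 (70.3%) had the opposite sign between the electroacupuncture group and suspension, 88 that rose with suspension and 59 that fell, and none passed in both. The share is not beyond that of simulated groups in which treatment changed nothing, with a mean of 68.3% (58.9% to 76.1% over 100 simulations). Without suspension arrays 1 and 2 it rested on 16 and 42 genes and was 87.5% and 81.0%. The median share of the suspension change that was returned was 0.110, against a simulated mean of 0.0919 and a highest of 0.128. These simulations called a mean of 741 genes for suspension minus control, against 209 in the data. Their values were taken over the 209 genes with the smallest p, so they match the data only in part. Across all genes the correlation of the suspension difference with the treatment difference was r = -0.33, against -0.50 from the shared arrays in simulated unchanged groups, and the covariance was -0.0185, against -0.0180. With 1 suspension array in each difference and none shared, r was 0.0327 and 0.0421.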

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

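Every alternative was chosen before the data were examined, except a crossed pairing of the replicate numbers of suspension and control. Counts of genes past the threshold are given for suspension minus control, treated minus suspended, and treated minus control, where they were 209, 0 and 206. With a constant variance prior the first and last were 80 and 101, with the groups compared fitted alone 68, 3 and 129, and with a block for replicate number 102, 0 and 127. The replicate numbers do not appear to pair the arrays (correlations across genes of the replicate differences -0.162, 0.0168 and -0.0157), and the crossed pairing, chosen after seeing the data, gave 266 for suspension minus control. Array weights gave 130 for the first and 4 for the second, a robust variance prior 1 for the second, and quantile normalization again 317 for the first. At an adjusted p under 0.10 the counts were 482, 1 and 399, through the looser threshold. With every transcript cluster by itself they were 1, 0 and 1. The larger number of tests alone lowered the first and last to 118 and 124. Noisier clusters also entered the variance prior, but their part in the further fall was not isolated. Leaving out each array in turn gave 16 to 301, 0 to 3 and 2 to 299; the lone array left in a group is assumed to vary like the other groups. For the other changed counts the cause was not tested.

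Of lists, 18, 13 and 19 were past the threshold with camera at the preset correlation and 0, 0 and 0 with an estimated correlation. The estimated setting also rests on 3 residual degrees of freedom, and the part of each in the lost calls was not isolated. With fry, which tests another hypothesis, 2, 1 and 4 were past it. No list past the threshold turned its direction with the arrays centred on their medians or with cyclic loess, the scalings under which lists were tested, whereas some lists that did not pass turned. Leaving out each array in turn gave 14 to 18, 8 to 15 and 17 to 20, and 10, 4 and 14 of the called lists kept their call throughout.

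The correlation of the suspension difference with the treatment difference, -0.33, was 0.0327 and 0.0421 when each difference used its own suspension array, which removes the shared array, and -0.52 to -0.26 without each array. The share of genes with the opposite sign, 70.3%, was 64.2% to 87.5% without each array.

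Among named genes no call turned sign. Differences that did not pass turned sign when an array was left out, and over the arrays left out they ran from -0.34 to 0.053 for Myh7 and from -0.10 to 0.41 for Trim63 in suspension minus control. In treated minus suspended the range was -0.74 to 0.34 for Myh2, -0.10 to 0.022 for Myh4, -0.0035 to 1.22 for Myog and -0.027 to 0.42 for Kera, and in treated minus control -0.22 to 0.18 for Myh7 and -0.40 to 0.15 for Chad. Of 47 named genes past the threshold with suspension, 8 kept their call without each array in turn. Signal over background limits genes near the level of the olfactory receptor genes, where folds depend on the background level.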

Other observations

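The tests of the clock, of the tendon genes and of the duplicate arrays were chosen after the results were seen. The lists of ATF4 and p53 targets were drawn up after the data were seen, but before the values of their members were looked at.

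Clock genes parted between the treated and the suspended arrays, with Dbp higher and Arntl lower. Without Dbp, Ciart, Arntl and Nfil3, which drew attention, 9 genes driven through E-boxes and D-boxes and 2 driven through ROR elements remained. Relative to the 2, the 9 lay 0.67 log2 higher in the treated than in the suspended arrays (0.53 to 0.81 over the 4 pairs of arrays). The clock list had already been called in this comparison and the pairs reuse the same arrays, so this value is not independent support. A shift of clock phase is a candidate explanation. The 4 suspended arrays had near-equal medians (4.18 to 4.19) and interquartile ranges (3.11 to 3.15), which argues against a scale difference between them. Cyclic loess therefore had little to remove, and the difference over all 11 and 4 members was 1.24 before and 1.24 after it. An effect of electroacupuncture, another time of day when the tissue was taken and chance cannot be told apart. The labels give no time of day, and no clock gene passed over all genes in the main fit. Dbp passed with array weights and with the groups compared fitted alone. The difference between the arms was 0.32 between suspension and control, where the control arrays had an SD of 0.347. The suspension and the treated arrays had SDs of 0.070 and 0.020.

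The tendon genes Chad, Kera and Tnmd fell with suspension, and Chad lay near its control level in the treated group. Less tendon carried over with the suspended samples might lower all 3. Chad minus the mean of Kera, Tnmd and Scx lay 1.23 log2 higher in treated than in control arrays (SE 0.29), but Chad was picked because it stood apart from the others, so the value decides nothing. Tendon carry-over, an effect of electroacupuncture on Chad (adjusted p = 0.0601) and chance cannot be told apart.

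The duplicate arrays of a group differed in markers of cell types. Adipocyte markers lay 1.17 log2 higher on control array 2 than on array 1 (SE 0.21 over members, 13 of 14 higher), and 1.12 after cyclic loess, which argues against a scale difference. Macrophage markers lay 0.73 higher on suspension array 1 than on array 2 (SE 0.06, 22 of 22 higher) and 0.49 higher on electroacupuncture array 1 than on array 2. These lists were picked because they differed, and their members are not independent of each other, so the SEs do not test the cause. Shifts of this size across whole lists argue against 1 RNA sample hybridized 2 times but do not exclude it. Separate animals and separate pieces of tissue cannot be told apart, since the labels name no animals.

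The rise of Chac1 and Slc43a1 with suspension led to the hypothesis that the ATF4 programme of amino acid stress was raised. The other 18 targets had a median of -0.067 log2 (quartiles -0.34 and 0.09, mean -0.09 ± 0.09 SE, 6 above 0, none past the threshold). These values argue against a general rise of these 18, whose members ran from -0.70 for Asns to 0.77 for Cth. The 4 targets that belong to the 37 lists were left out, so the values do not cover them. The atrophy gene Gadd45a, which rose with suspension, was not among the 18 either. A rise of part of the programme therefore stays open.

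Eda2r and Gadd45b led to the hypothesis of a raised p53 programme. The other 15 targets had a median of 0.0093 log2 (quartiles -0.11 and 0.34, mean 0.07 ± 0.11 SE, 8 above 0), and 1 of them, Trp53inp1, rose by 1.00 (adjusted p = 0.0394). The bound set beforehand, on the median and mean, was met, but it was too weak to decide, as members went both ways with an upper quartile of 0.34 and the list lacked Gadd45a, a p53 target that rose by 1.24. The hypothesis stays open. The 3 targets in the 37 lists were left out.

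These values were chosen after they were seen. Suspension arrays 1 and 2 had signals of 10.02 and 4.09 for Mmp13, 10.07 and 6.25 for Serpina3n, 6.98 and 4.04 for Timp1, 10.85 and 7.92 for Fn1 and 7.41 and 4.95 for Postn. Control arrays 1 and 2 had 5.16 and 8.58 for Nnat and 5.10 and 8.09 for Adipoq. Cish had 4.73 and 7.44 on the control arrays and 3.87 and 7.21 on the electroacupuncture arrays.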
